A study of Mus musculus with 5 samples.

How the data were processed

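RNA-seq libraries of cultured mouse epidermal stem cells were compared between Angptl4 knockout (KO, 2 libraries) and wild-type (WT, 3 libraries) cells, with each library's group taken from its title. The authors deposited 1 table of 17657 protein-coding genes with expected counts, TPM and FPKM per library. Per the submitters' processing notes, the deposited expected counts were estimated with RSEM 1.3.1 on the GRCm38.p6 build. RSEM divides reads that match several genes or transcripts by probability, so counts need not be whole (32.1 to 34.0% of values per library were not), and genes with close copies share reads. The deposited TPM values are, per the file headers, scaled by transcript length and within each library by the authors. The aligner and the strand setting are not given in the sources used here. The 5 FPKM columns were not used here, and no column belonged to a sample outside the labels. The table lists 0 mitochondrial genes, so a mitochondrial share was not computed. Of the gene identifiers 17607 were matched in a RefSeq gene table of the same build, 13059 with the same start and end, and coordinates are those of the deposited table.

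Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out with edgeR's filterByExpr by group, libraries were scaled with TMM factors (0.988 to 1.02), and KO was compared with WT by the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. CPM values use the library totals and TMM factors, and standard errors were derived from the test statistic. Totals ranged from 20283084 to 20773407 counts per library, so 1 CPM stands for about 20 counts, and counting intervals (95%, exact binomial on the summed counts) cover counting error only.

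Before the data were examined, 22 pathway and 8 cell type lists, the test of genes near Angptl4, the tests and most alternatives were fixed. The pathway lists cover keratinocyte adhesion, hair follicle stem cells, terminal differentiation, wound keratinocytes, DNA replication, mitosis, G1 cyclins and inhibitors, p53, integrins, Wnt, EGFR and MAPK, TGF-beta, proteases, fatty acid oxidation, sterol and fatty acid synthesis, hypoxia and glycolysis, inflammation, interferon, class II presentation, unfolded protein, NRF2 and oxidative phosphorylation. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and adjusted over the lists of a kind. With the correlation estimated for each list, none of the 12 pathway lists and 1 cell type list that passed kept its call. That correlation was estimated from the spread among 5 libraries, and this setting was not run on the simulated counts described below. Whether it could pass a true change here is not known, so a call lost there does not show that a list was unchanged. Named genes are Angptl4, the 10 genes with the largest rise and the 10 with the largest fall among those with adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between groups, and for each list the members with the smallest p, up to 4 per pathway and 2 per cell type list. Predicted genes and pseudogenes were to be left out of the largest changes, and 0 were. Cxcl2, Cxcl3, Cxcl5 and Postn fall under both parts of the rule. Some genes that the rule takes are not reported here. Krt5, Krt14, Col1a1, Dcn, Sparc, Fbln1, Fbln2 and the genes under other observations were chosen after their values were seen.

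The alternatives were DESeq2's size factors, total count scaling, DESeq2 1.42.0, limma-voom, no count filter, a stricter filter (a group mean of at least 10 and an overall mean of at least 50 counts), the replicate number as a block, each library left out, limma on log2(TPM + 1) with and without a minimum mean TPM of 1 and on log2(TPM + 0.1), camera with an estimated correlation, the rotation test fry, and windows of 5 and 20 Mb. The comparison of genes near Angptl4 left out Angptl4 itself and genes on unplaced scaffolds. A limma-voom fit with a separate spread per group, and fry for the cell type lists, were added after the data were seen. Where 1 KO library was left, it was assumed to vary like the WT libraries. Counting the members of each list among the genes tested in each fit, and of the KEGG pathways and gene families under other observations, with each library left out was decided after the data were seen.

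WT pairs differed by more than counting noise (chi-square over degrees of freedom 3.42 to 6.38) and the KO pair by far more (108), so no library was counted as a copy of another. The first principal component of log2 CPM took 72.8% of the variance and separated the groups, and the second took 18.7% and separated KO1 from KO2.

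The test was run on simulated counts drawn for the KO against WT comparison from the real means and library sizes, with 200 genes changed. With 1 spread for all libraries, edgeR on 12801 genes recovered 70.1% of the 2-fold and 98.0% of the 4-fold changes, and 5.7% of its calls were false. With the spread of each group as measured, on 12800 genes, it recovered 36.4% of the 2-fold and 84.8% of the 4-fold changes and 17.2% of its calls were false, above the 5% aimed for. The fit with a spread per group made 12.5% false calls there. The edgeR test was kept as the main test because it had been fixed beforehand. The share of false calls among the real calls is not known from these simulations, which held fewer changed genes. In the same simulations camera called the 1 list of shifted genes and 0 of the others. Genes were drawn independently there and the other lists were random, so false calls of lists with correlated genes could not be seen.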

Results

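RNA was sequenced from epidermal stem cells, the keratinocyte progenitors of the skin surface and hair follicle, taken from the skin of male C57BL/6 mice labelled 8 weeks and grown in KGM2, a keratinocyte growth medium. Cells of wild-type mice (WT, 3 libraries) were compared with cells of mice lacking Angptl4 (KO, 2 libraries), a gene for a secreted protein that inhibits lipoprotein lipase. The libraries held 20773407, 20714973 and 20686246 expected counts in WT1, WT2 and WT3 and 20507641 and 20283084 in KO1 and KO2. The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The basal keratin Krt5 alone took 1.65 to 1.71% of the counts in the WT libraries and 2.44 and 1.88% in KO1 and KO2.

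The first question was whether the targeted gene was lower in the libraries labelled KO. Angptl4 (NCBI gene 57875, GRCm38.p6 chromosome 17, 33774900 to 33781575, minus strand) was measured at 6.97, 5.76 and 4.13 CPM (counts scaled by library size) in WT1, WT2 and WT3 and at 0.83 and 1.06 CPM in KO1 and KO2. It fell by 2.56 ± 0.32 (SE) on the log2 scale, 5.89-fold (adjusted p = 0.00458 by edgeR's quasi-likelihood test), and both KO libraries lay below every WT library. These values rest on 347 counts over the WT and 39 over the KO libraries, and the part of the gene removed in the KO allele is not given in the sources used here. With a separate spread for each group, a fit chosen after the KO libraries were seen to vary more, the change did not pass (adjusted p = 0.127; range over its alternatives 5.68e-09 to 0.127).

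The comparison the series was designed for is KO against WT over all genes. In the KO cells 30 of 32 DNA replication genes and 22 of 31 mitosis genes fell, while 10 of 16 fibroblast markers, 14 of 24 interferon-response genes and 14 of 23 genes of fatty acid oxidation and PPAR targets rose. Each of these lists passed the camera test with a preset correlation, and none did with an estimated correlation (adjusted p = 0.543 to 0.942 with an estimated correlation). Without WT1, WT2 or WT3 the genes that fell numbered 27, 27 and 27 for DNA replication and 2, 3 and 2 for mitosis. Those that rose numbered 4, 6 and 4 for fibroblast markers, 5, 7 and 8 for interferon and 5, 6 and 6 for fatty acid oxidation. Of 12957 genes tested, 5286 (40.8%) changed, 2638 higher and 2648 lower in KO. Counts of list members, here and below, are to be read against these numbers over all tested genes. A change of at least 2-fold was found for 1807 genes, 1144 higher and 663 lower. In all 5286 the KO and WT libraries did not overlap; among all tested genes 66.4% did not overlap, where chance gives 20%. The count was 1957, 2282 and 2244 genes without WT1, WT2 or WT3, 8068 without KO2, and 3192 with a separate spread per group. At least 2-fold changes numbered 981, 1100 and 1076 without WT1, WT2 or WT3. For the lists fixed beforehand, counts of members past the threshold were repeated with WT1, WT2, WT3, KO1 and KO2 left out in turn, and are given in that order where any differs by over 1.5 times. The KO libraries varied far more than the WT libraries (biological coefficient of variation 28.8 against 5.21%), and in data simulated with those spreads 17.2% of the calls of the test used were false.

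**Figure D1:**
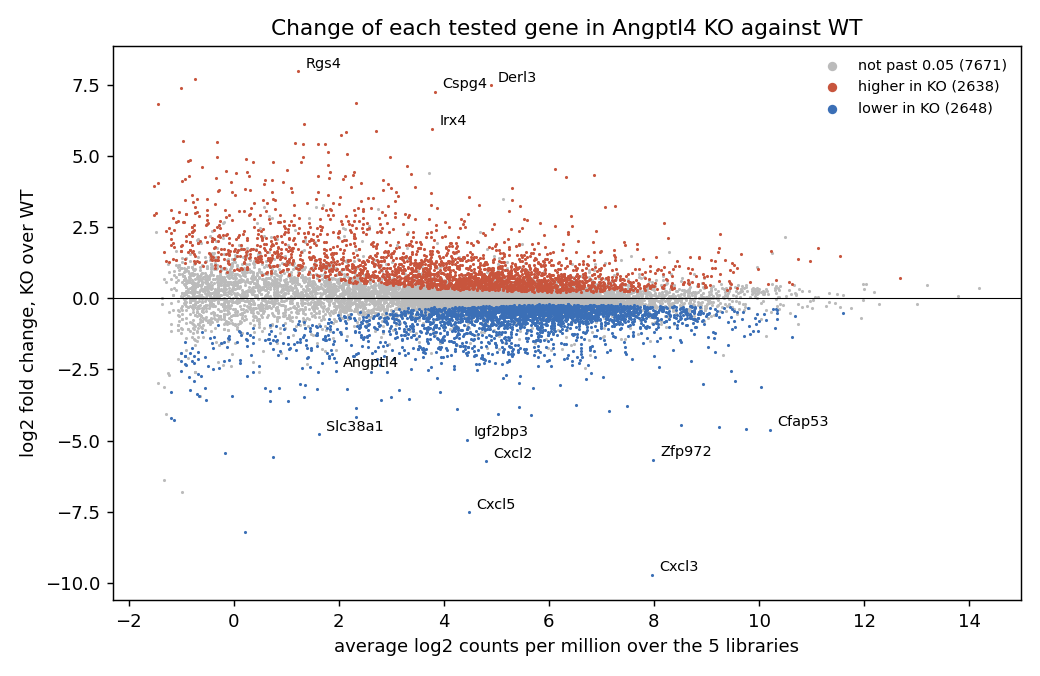
Log2 fold change of each tested gene in KO over WT (vertical axis) against its average log2 CPM over the 5 libraries (horizontal axis). Red points are the 2638 genes higher and blue points the 2648 genes lower in KO, grey points did not pass, and Angptl4 with 11 of the genes of largest change are named.

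The 10 genes with the largest rise were at 0.02 to 0.53 CPM in WT. Cspg4, a cell surface proteoglycan (chromosome 9, 56865104 to 56899870), was at 0.23 ± 0.03 CPM (SD, n = 3) in WT and 35.2 ± 13.3 CPM (SD, n = 2) in KO, a log2 rise of 7.24 ± 0.35 (adjusted p = 0.00084). Postn, which encodes the matrix protein periostin, rose by 6.87, the collagens Col5a2 and Col6a2 by 6.11 and 5.44, and the proteoglycan Bgn by 5.88. Postn and Col6a2 are also members of the fibroblast marker list, whose median log2 change was 2.70. Irx4, a homeobox transcription factor, rose by 5.95 (0.53 to 33.3 CPM), and Medag and the neurotrophic receptor Gfra2 by 5.83 and 5.73. Among these, Postn was at 17.2 CPM in KO1 and 7.01 CPM in KO2, Col6a2 at 7.88 and 2.46 CPM and Medag at 5.24 and 15.7 CPM. For 2 of the 10 genes 1 KO library set the value. Derl3, of endoplasmic reticulum-associated degradation, was at 1.52 CPM in KO1 and 145 CPM in KO2. Rgs4, a regulator of G protein signalling, was at 10.5 CPM in KO1 and 0.68 CPM in KO2, and with 1 count over the WT libraries its ratio of KO to WT was 349 (95% counting interval 62.0 to 13850). The rise of Derl3 was 1.90 without KO2 and that of Rgs4 4.93 without KO1. Neither call held without WT1, WT2 or WT3 (adjusted p = 0.0794, 0.0766 and 0.111 for Rgs4, range over its alternatives 5.7e-06 to 0.166, and 0.107, 0.106 and 0.111 for Derl3, range 9.2e-08 to 0.388).

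Of the 10 genes with the largest fall 3 were chemokines. Cxcl3 (chromosome 5, 90786101 to 90788093), which attracts neutrophils, was at 416 ± 61.4 CPM (SD, n = 3) in WT and 0.49 ± 0.42 CPM (SD, n = 2) in KO, a log2 change of -9.72 ± 0.45 (adjusted p = 0.00084). Its neighbours Cxcl5 and Cxcl2 changed by -7.52 and -5.73 on the log2 scale. Igf2bp3, an RNA-binding protein of fetal tissues, changed by -4.97 (35.2 to 1.12 CPM), and the glutamine transporter Slc38a1 by -4.77. The other 5 were Zfp972 (-5.68), the cilia gene Cfap53 (-4.63), the olfactory receptor Olfr1033 (-4.58), Wdr92 (-4.53) and the zinc finger gene Zbtb8b (-4.45), at 415 to 1920 CPM in WT. Zfp972 and Olfr1033 have close copies in the genome and Wdr92 overlaps a neighbouring gene, so which gene their reads came from is uncertain. Reads shared with other loci were not resolved for Cfap53 and Zbtb8b either.

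**Figure D2:**
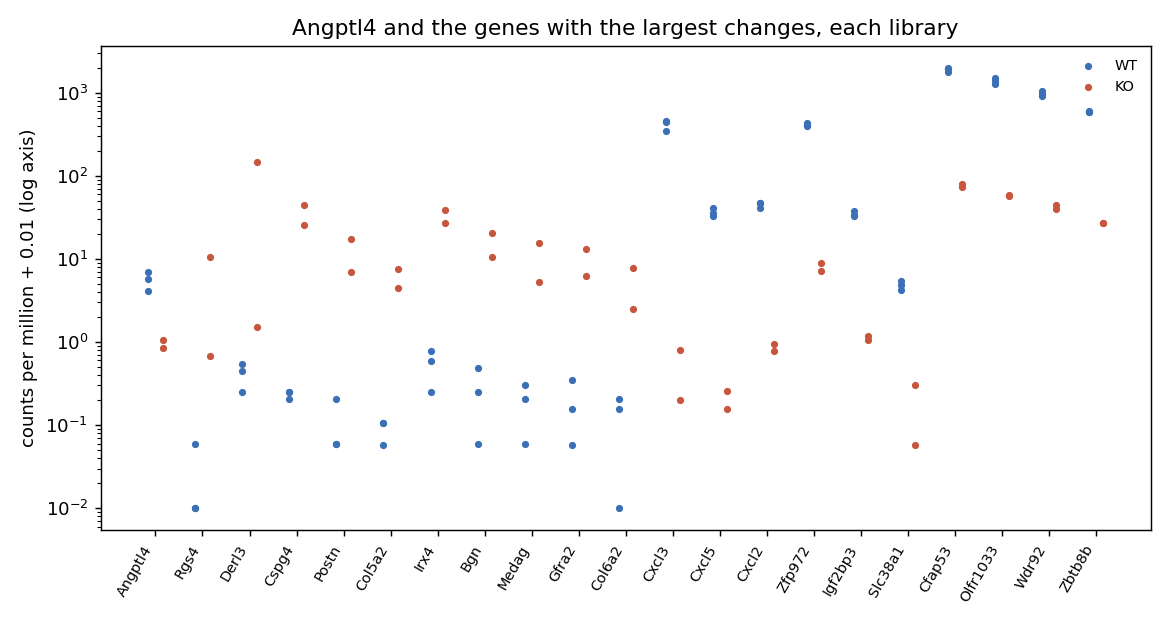
CPM plus 0.01 on a log axis (vertical) for Angptl4 and the 10 genes with the largest rise and the 10 with the largest fall (horizontal), one point per library, blue WT (3) and red KO (2), with libraries at 0 drawn at 0.01. Derl3 stands at 1.52 CPM in KO1 and 145 CPM in KO2.

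Genes of DNA replication were lower in the KO cells almost without exception. Of 32 members of the list, 30 fell, 0 rose and 2 did not pass, and 30 fell adjusted over the list alone (median log2 change -1.50). Cdt1, which licenses replication origins, changed by -1.51 (70.0 to 24.5 CPM), the polymerase subunit Pola1 by -1.77 and the S-phase cyclin Ccne2 by -2.49. Among 31 mitosis genes 22 fell, 0 rose and 9 did not pass, and 30 fell adjusted over the list alone. The checkpoint gene Bub3 changed by -0.88 and the cytokinesis gene Ect2 by -1.83. Mitosis genes differed between the KO libraries, with list medians of -1.14 in KO1 and -3.02 in KO2, against -1.21 and -1.78 for DNA replication. For mitosis genes with 1 library left out, the 22 lower became 2, 3, 2, 31 and 31. Both lists passed the camera test (adjusted p = 1.9e-13 and 1.6e-07), and neither call held with an estimated correlation (adjusted p = 0.543 and 0.653 with an estimated correlation). The mitosis call was also lost with the rotation test fry (adjusted p = 0.0933; range over its alternatives 1e-17 to 0.653).

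Among cell cycle inhibitors, Cdkn2a, which encodes p16 and p19, rose from 0.16 to 7.13 CPM (log2 change 5.41 ± 0.79, adjusted p = 0.00642), with 11.6 CPM in KO1 and 2.66 CPM in KO2. Its neighbour Cdkn2b rose from 6.41 to 42.0 CPM, with 55.2 CPM in KO1 and 28.9 CPM in KO2, while the pocket protein gene Rbl1 changed by -1.05. Of the 17 members of the list of G1 cyclins and inhibitors 5 rose, 4 fell and 8 did not pass, the same counts adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.724). With 1 library left out, the 5 higher became 3, 3, 3, 6 and 8 and the 4 lower became 1, 1, 1, 5 and 7. Of 22 p53 targets 10 rose, 2 fell and 10 did not pass, with 11 and 2 adjusted over the list alone. The BH3-only genes Pmaip1 and Bbc3, which promote apoptosis, rose by 1.35 and 2.30, and Btg2, an antiproliferative gene, by 1.22. The list passed (adjusted p = 0.0147; adjusted p = 0.577 with an estimated correlation) but not without KO2 (adjusted p = 0.0774; range over its alternatives 0.00116 to 0.577). For p53 targets with 1 library left out, the 10 higher became 5, 5, 6, 15 and 12 and the 2 lower became 0, 0, 0, 3 and 4.

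Lipid genes were followed in 2 lists. Of 34 genes of sterol and fatty acid synthesis 16 fell, 0 rose and 18 did not pass, the same counts adjusted over the list alone. The cholesterol enzymes Dhcr7 and Hsd17b7 changed by -1.31 and -1.29. The list medians were -0.54 in KO1 and -1.67 in KO2. With 1 library left out, the 0 higher became 0, 0, 0, 0 and 4 and the 16 lower became 2, 3, 3, 32 and 26. Of 23 genes of fatty acid oxidation and PPAR targets, the group closest to the known function of Angptl4, 14 rose, 2 fell and 7 did not pass, with 15 and 2 adjusted over the list alone. Acadl and Decr1, which act in mitochondrial beta-oxidation, rose by 1.22 and 1.10, and the carnitine transferase Cpt1a by 1.11 (26.5 to 57.1 CPM). For these oxidation genes with 1 library left out, the 14 higher became 5, 6, 6, 15 and 17 and the 2 lower became 0, 0, 1, 3 and 4. The lists passed with adjusted p = 3.1e-05 and 0.00356, against adjusted p = 0.781 and 0.543 with an estimated correlation. The synthesis list was also lost with fry (adjusted p = 0.132; range over its alternatives 2.1e-14 to 0.781).

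Of 32 hypoxia and glycolysis genes 12 rose, 1 fell and 19 did not pass, the same counts adjusted over the list alone. The glucose transporter Slc2a1 rose by 1.25 (464 to 1101 CPM), the phosphofructokinase Pfkp by 0.85 and the mitophagy gene Bnip3 by 1.07. The list passed (adjusted p = 0.0251; adjusted p = 0.543 with an estimated correlation), but not without KO1 (adjusted p = 0.0723; range over its alternatives 0.00387 to 0.543). For glycolysis genes with 1 library left out, the 12 higher became 5, 5, 6, 16 and 18 and the 1 lower became 0, 0, 0, 7 and 2. Of 36 oxidative phosphorylation genes 7 fell, 0 rose and 29 did not pass, with 4 lower adjusted over the list alone. These 7 were no larger a share than the 2648 of 12957 tested genes that were lower over all. The median log2 change was -0.22, with -0.07 in KO1 and -0.36 in KO2. That list passed (adjusted p = 0.0147; adjusted p = 0.80 with an estimated correlation), but not with DESeq2 (adjusted p = 0.10), with fry (adjusted p = 0.158) or without KO2 (adjusted p = 0.401; range over its alternatives 1.8e-05 to 0.80). For oxidative phosphorylation with 1 library left out, the 0 higher became 0, 0, 0, 0 and 7 and the 7 lower became 0, 1, 0, 27 and 11. Of 22 oxidative stress and NRF2 targets 5 fell, 1 rose and 16 did not pass, the same counts adjusted over the list alone, with Txnrd1, a thioredoxin reductase, at 201 CPM in WT and 56.9 CPM in KO. The list passed narrowly (adjusted p = 0.0414; adjusted p = 0.543 with an estimated correlation) and not without KO2 (adjusted p = 0.0939) or with a stricter count filter (adjusted p = 0.169; range over its alternatives 0.00765 to 0.543). For NRF2 targets with 1 library left out, the 1 higher became 0, 0, 0, 2 and 4 and the 5 lower became 3, 3, 3, 12 and 11.

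Of 28 inflammatory cytokine and NF-kappaB genes 9 fell, 5 rose and 14 did not pass, the same counts adjusted over the list alone. Beside Cxcl2, Cxcl3 and Cxcl5, the alarmin Il1a changed by -2.78 (198 to 28.8 CPM). The list passed (adjusted p = 0.0283; adjusted p = 0.653 with an estimated correlation) but not without KO2 (adjusted p = 0.149) or with a separate spread per group (adjusted p = 0.079; range over its alternatives 9.6e-05 to 0.653). With 1 library left out, the 5 higher became 2, 3, 2, 6 and 8 and the 9 lower became 7, 7, 8, 16 and 14. Of 24 interferon-response genes 14 rose, 0 fell and 10 did not pass, with 15 higher adjusted over the list alone (median log2 change 1.03). The antiviral Oas3 rose by 4.15 (0.91 to 16.2 CPM), the transcription factor Irf7 by 2.32 and the peptide transporter Tap1 by 1.68 (40.4 to 129 CPM). That list passed with adjusted p = 0.00019, against adjusted p = 0.543 with an estimated correlation. For interferon genes with 1 library left out, the 14 higher became 5, 7, 8, 17 and 18. Of 5 tested genes of class II antigen presentation 3 rose, 0 fell and 2 did not pass, with 4 higher adjusted over the list alone, and H2-Ab1 rose from 0.60 to 7.51 CPM, with 10.6 CPM in KO1 and 4.45 CPM in KO2. The list passed (adjusted p = 0.0259; adjusted p = 0.543 with an estimated correlation) but not without KO1 (adjusted p = 0.0586; range over its alternatives 0.011 to 0.543).

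Of 28 genes that respond to EGFR and MAPK signalling 7 fell, 2 rose and 19 did not pass, with 7 and 1 adjusted over the list alone. The immediate early gene Fosb changed by -3.75 (146 to 10.8 CPM), the EGFR ligand Tgfa by -1.88 and Phlda1 by -1.48. The list medians were -1.18 in KO1 and -0.27 in KO2. The list passed (adjusted p = 0.0147; adjusted p = 0.80 with an estimated correlation) but not with fry (adjusted p = 0.143) or without KO1 (adjusted p = 0.13; range over its alternatives 7.2e-05 to 0.80). For EGFR and MAPK genes with 1 library left out, the 2 higher became 0, 1, 0, 5 and 3 and the 7 lower became 3, 4, 4, 11 and 18.

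**Figure D3:**
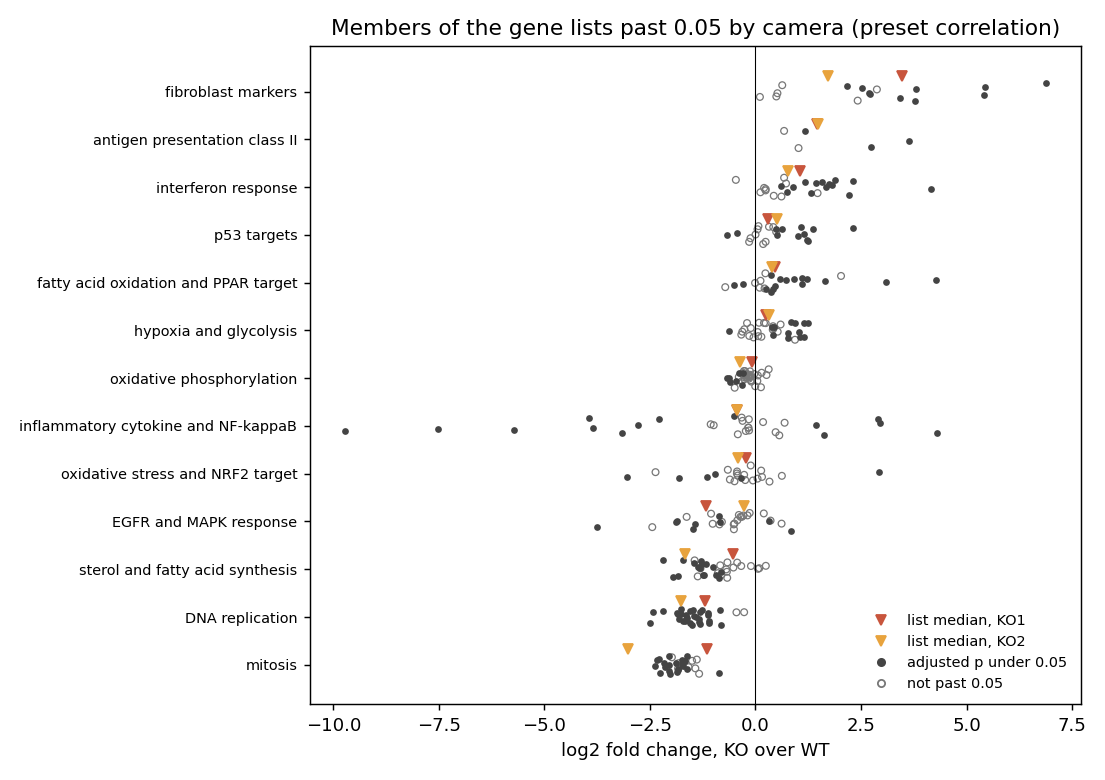
Log2 fold change in KO over WT (horizontal axis) of each tested member of the 13 lists that passed the camera test with the preset correlation (vertical axis), filled where the gene passed and open where it did not, with triangles for the list median in KO1 (red) and KO2 (orange) against the WT mean. The mitosis medians lie at -1.14 in KO1 and -3.02 in KO2.

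The lists of keratinocyte identity, differentiation and wound response did not pass the camera test. Of 26 genes of keratinocyte adhesion and the basal layer 5 rose, 5 fell and 16 did not pass, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.735). The median log2 change of this list was -0.04 and its mean 0.04, and camera gave the lower direction. With 1 library left out, the 5 higher became 0, 0, 1, 6 and 13 and the 5 lower became 2, 2, 2, 12 and 10. The basal integrin Itga6 changed by -0.91 (1206 to 640 CPM) and the epidermal master regulator Trp63 by -0.73. The adhesion molecule gene Cdh1 rose by 0.56 (766 to 1130 CPM, adjusted p = 0.00703), but its call was lost without WT1, WT2 or WT3 (highest adjusted p = 0.0605; range over its alternatives 1.3e-17 to 0.147). Krt5 and Krt14 did not pass (log2 changes 0.35 and 0.07). Of 40 terminal differentiation genes 7 rose, 6 fell and 27 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.987). The median log2 change of that list was 0.04 and its mean 0.31, while camera gave the lower direction, and the medians were -0.60 in KO1 and 0.49 in KO2. Notch3, a receptor of the differentiation programme, rose by 1.52 and the ceramide synthase Cers3 changed by -0.88. For terminal differentiation with 1 library left out, the 7 higher became 2, 2, 2, 16 and 8 and the 6 lower became 2, 2, 2, 8 and 20. Of 16 wound and stress keratinocyte genes 2 rose, 4 fell and 10 did not pass, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.53), and the protease inhibitor Slpi changed by -2.16. Lcn2, an iron-binding protein of inflamed skin, rose by 3.24 (1.73 CPM in WT, 6.95 and 25.8 CPM in KO1 and KO2), and its call was lost without WT1, WT2 or WT3 (highest adjusted p = 0.0574; range over its alternatives 2.4e-07 to 0.0574). For wound genes with 1 library left out, the 2 higher became 0, 0, 0, 2 and 5 and the 4 lower became 3, 4, 4, 7 and 6.

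The hair follicle stem cell and integrin lists did not pass the camera test, while single members changed. Of 17 hair follicle stem cell genes 7 rose, 2 fell and 8 did not pass, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.14). The infundibular marker Plet1 changed by -2.57 (1064 to 179 CPM), while Tbx1, Gas1 and the stem cell factor Sox9 rose by 3.88, 3.08 and 0.66. Of 25 integrin, fibronectin and focal adhesion genes 5 rose, 6 fell and 14 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.724). The collagen receptor subunit Itga2 changed by -1.88 (813 to 220 CPM), and the matrix protein Tnc rose by 2.63 (95.1 to 589 CPM). Integrin genes had a median log2 change of -0.19 and a mean of 0.04, with camera in the lower direction. For integrin genes with 1 library left out, the 5 higher became 2, 2, 2, 7 and 12 and the 6 lower became 3, 3, 3, 12 and 10.

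The Wnt, TGF-beta, protease and stress response lists did not pass the camera test either. Of 17 Wnt targets 5 rose, 2 fell and 10 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.696), with the receptor Fzd7 higher by 2.17 and Znrf3, a negative regulator of Wnt receptors, lower by a log2 change of -0.78. With 1 library left out, the 5 higher became 4, 3, 3, 6 and 9 and the 2 lower became 1, 1, 1, 6 and 3. Of 22 TGF-beta and mesenchymal transition genes 7 rose, 2 fell and 13 did not pass, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.696). For TGF-beta genes with 1 library left out, the 7 higher became 1, 1, 2, 6 and 12 and the 2 lower became 0, 0, 2, 7 and 5. Of 21 extracellular protease genes 7 rose, 2 fell and 12 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.393, but 0.019 in the higher direction with fry; range over its alternatives 0.019 to 0.782), with Mmp2 higher by 2.06 and Plaur lower by a log2 change of -1.19. For proteases with 1 library left out, the 7 higher became 4, 4, 4, 8 and 9 and the 2 lower became 1, 1, 2, 7 and 7. Of 22 unfolded protein and integrated stress genes 6 rose, 3 fell and 13 did not pass, the same counts adjusted over the list alone, with medians of -0.22 in KO1 and 1.38 in KO2. That list did not pass (adjusted p = 0.696), and without KO1 it did (adjusted p = 0.00042; range over its alternatives 0.00042 to 0.943). For stress response genes with 1 library left out, the 6 higher became 0, 0, 0, 15 and 8 and the 3 lower became 0, 0, 0, 4 and 11.

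Markers of other skin cell types were compared because a skin culture can hold them. Of 16 tested fibroblast markers 10 rose, 0 fell and 6 did not pass, the same counts adjusted over the list alone (median log2 change 2.70, with 3.47 in KO1 and 1.72 in KO2). Col6a1 rose by 5.42, to 8.27 CPM in KO1 and 3.29 CPM in KO2. Col1a1 was at 1.07 CPM in WT and at 18.9 and 4.20 CPM in KO1 and KO2, and the fibroblast proteoglycan gene Dcn at 0.83 CPM in KO. Of the members that did not pass, Fbln2 was at 391 CPM in WT and 420 CPM in KO, Fbln1 at 51.8 and 74.2 CPM and Sparc at 25.1 and 35.4 CPM. The list passed (adjusted p = 0.00056; adjusted p = 0.942 with an estimated correlation) but not with fry (adjusted p = 0.15) or without KO1 (adjusted p = 0.106; range over its alternatives 1.3e-05 to 0.942). For fibroblast markers with 1 library left out, the 10 higher became 4, 6, 4, 8 and 16 and the 0 lower became 0, 0, 0, 1 and 0. Keratinocyte markers did not shift (3 rose, 1 fell and 10 did not pass, with 2 and 1 adjusted over the list alone; adjusted p = 0.657), but did without KO2 (adjusted p = 0.044; range over its alternatives 0.044 to 0.942). For keratinocyte markers with 1 library left out, the 3 higher became 0, 0, 0, 3 and 9 and the 1 lower became 1, 1, 1, 3 and 2. Melanocyte (1 rose of 6), endothelial (1 rose and 1 fell of 5), immune (1 rose of 5) and gland (2 rose and 1 fell of 8) lists did not pass (adjusted p = 0.70, 0.838, 0.891 and 0.891), with the same counts adjusted over each list alone. Immune markers had a median log2 change of 0.13 and a mean of -0.89, with camera in the higher direction, and gland markers a median of -0.08 and a mean of 0.01, with camera in the lower direction. For melanocyte markers with 1 library left out, the 1 higher became 1, 1, 1, 2 and 1. For endothelial markers the 1 higher became 0, 0, 0, 0 and 2 and the 1 lower became 0, 0, 0, 1 and 2. For immune markers the 1 higher became 0, 1, 0, 1 and 1 and the 0 lower became 0, 0, 1, 0 and 0. For gland markers the 2 higher became 0, 0, 0, 2 and 1 and the 1 lower became 0, 1, 1, 1 and 3. Too few members were tested of the Merkel and simple epithelial list (0 rose and 2 fell of 3, with 1 and 2 adjusted over the list alone) and of the muscle, adipose and erythroid list (1 rose of 2, also adjusted over the list alone). In the Merkel list with 1 library left out, the 0 higher became 0, 0, 0, 0 and 1 and the 2 lower became 0, 1, 0, 1 and 2, and in the muscle list the 1 higher became 0, 0, 0, 1 and 3. The smooth muscle actin Acta2, the member that rose, was at 243 CPM in WT and at 1746 and 581 CPM in KO1 and KO2, and its call was lost without WT1, WT2 or WT3 (highest adjusted p = 0.0676; range over its alternatives 4.6e-07 to 0.0676).

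A knockout allele can carry flanking sequence of the strain it was made in, so genes within 10 Mb of Angptl4 were compared with all others. Of 315 such genes 118 (37.5%) changed, against 40.9% of the other tested genes, and the share was not higher (Fisher's exact test, one-sided, p = 0.90). Genes of the major histocompatibility complex lie in this window, among them H2-Ab1 and Tap1, which rose. The odds of change in the window were above those elsewhere without WT1, WT2 or WT3 (Fisher's exact test, p = 0.123, 0.0721 and 0.139), and the test did not pass in any of these.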

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

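No group was large enough to test for an outlying library, and the design holds 1 contrast. The tests for the flanking sequence over all genes and for markers of other cells over all genes were fixed beforehand, and the other tests here, and the reading of which fibroblast markers count as abundant, were chosen after the result was seen.

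The KO libraries differed from each other more than the WT libraries did. Between KO1 and KO2, mitosis genes differed by a median of 1.75 on the log2 scale (higher in KO1). Sterol and fatty acid synthesis genes differed by 1.15 and unfolded protein genes by -1.63 (lower in KO1). The median size of each difference lay above all 10000 random lists matched on expression, which describes these libraries alone. So did that of terminal differentiation (1.15), EGFR and MAPK (0.929), TGF-beta (0.9), inflammatory (0.832) and DNA replication genes (0.529). Random lists hold unrelated genes, so a list whose genes vary together can exceed them. Counting error is argued against by genes with a mean of at least 1000 counts, where the KO pair still differed by a median of 0.219 (log2) against 0.051 to 0.059 for the WT pairs, and a trend on GC content and transcript length, available for 98.1% of tested genes, took 0.29% of the variance of the difference. WT libraries made from 1 culture, which would make the WT spread technical and the p-values too small, cannot be told apart from separate cultures: the least different WT pair had a chi-square over degrees of freedom of 3.42, above counting noise and below the KO pair, and the labels do not name the cultures. The labels name no difference between KO1 and KO2, so no biological explanation was tested for these values.

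Of 16 fibroblast markers 10 rose in KO, and 3 of them reached 10 CPM as a mean of the KO libraries. These 3, Postn, Col1a1 and Thy1, were at 17.2, 18.9 and 15.0 CPM in KO1 and 7.01, 4.20 and 5.80 CPM in KO2. The median log2 change of the list was 2.70, with 3.47 in KO1 and 1.72 in KO2. The list passed camera with a preset correlation but not with an estimated one (adjusted p = 0.942 with an estimated correlation), with fry (adjusted p = 0.15) or without KO1 (adjusted p = 0.106; range over its alternatives 1.3e-05 to 0.942). Dilution by other cells is argued against for the genes that fell at least 2-fold: that needs keratinocyte markers lower by at least 1 (log2), and their lower quartile was -0.042. For the risen markers the test leaves fibroblasts in the KO cultures open, since the excess in KO2 relative to KO1 ranged from 0.175 to 0.414 over markers with at least 20 excess counts in KO1, more than counting error allows (chi-square over degrees of freedom 4.25) and less than the 3-fold range set to exclude it. A change of the keratinocytes themselves in KO stays open as well, and Sparc, Fbln1 and Fbln2 of the same list were also at 25.1 to 391 CPM in WT.

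In KO 14 of 24 interferon-response genes and 3 of 5 class II genes rose, and part of them lie near Angptl4. Both lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.543 with an estimated correlation for both), and class II not without KO1 (adjusted p = 0.0586; range over its alternatives 0.011 to 0.543). Sequence kept around the KO allele is argued against as a local effect for 11 of the 14 risen interferon members, which lie elsewhere. Among them are Irf7 and Oas3. The other 3, Psmb8, Psmb9 and Tap1, lie in the window, so the explanation stays open for them. This division is set by where the listed genes lie, and an effect of kept sequence on genes elsewhere was not tested. For class II all 3 risen members lie in the window and 1 tested member lies elsewhere, so the explanation cannot be told apart from a response of the cells. Over all changed genes the planned test found no excess in the window (Fisher's exact test, p = 0.90). The share there was 37.5%, against 40.9% elsewhere, and a share at or below that elsewhere was set beforehand as counting against the explanation. The interval of the share in the window (32.1 to 43.1%), not part of that prediction, includes the share elsewhere, so a contribution stays open.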

How the results depend on the processing

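DESeq2's size factors, total count scaling, DESeq2, limma-voom and both count filters gave 4828 to 5698 changed genes against 5286, and no called gene changed sign under these. No called gene changed sign without any 1 library either. That was nearly fixed in advance, since the KO and WT libraries did not overlap in any of the 5286. The fit with a spread per group, chosen after the data were seen, gave 3192 (1625 higher, 1567 lower) and kept 3107 of the calls; there Angptl4 (-2.51) did not pass. The replicate number as a block gave 1598 (804 higher, 794 lower), 1116 of them at least 2-fold, and 1580 of the calls were shared. WT3 has no KO library of its number, so it does not inform the fitted change there. That fit therefore compares fewer libraries than the main test. With correlations of 0.007 and 0.068 for the 2 same-numbered pairs, the numbers are not taken to pair the samples. On log2(TPM + 1) 2089 genes were higher and 2736 lower (43.3% higher, against 49.9%), and 1 called gene changed sign. At least 2-fold changes there numbered 1134, and 1053 with no filter; the pseudocount shrinks low genes.

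Leaving out 1 library gave 1957 to 8068 changed genes (977 to 4093 lower, 980 to 3975 higher), and 981 to 2275 at least 2-fold; counts rose without a KO library, where the WT libraries alone give the spread, and fell without a WT library, for which the cause was not tested. Cell type lists past the threshold ranged from 0 to 2. The p for genes near Angptl4 ranged from 0.0721 to 0.995, with the direction reversed without any 1 WT library, under the block (0.0922) and with a spread per group (0.215); the cause was not tested.

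With an estimated correlation 0 pathway and 0 cell type lists passed, and with fry 9 pathway and 0 cell type lists. Lists that changed direction had not passed in the main test. Terminal differentiation reversed with DESeq2 (adjusted p = 0.716), a spread per group (0.92) and fry (0.846), immune markers with no filter (0.476) and under the block (0.539), and gland markers with no filter (0.845) and fry (0.649). Other reversals came with 1 library left out, each in at least 1 of these fits. The brackets span all of these fits, also those that kept the direction. The lists were terminal differentiation (0.261 to 0.943), immune (0.561 to 0.996), gland (0.667 to 0.996), endothelial (0.561 to 0.996) and Wnt (0.243 to 0.963). Further ones were TGF-beta (0.0999 to 0.963), basal adhesion (0.327 to 0.802), wound (0.171 to 0.992), integrin (0.328 to 0.771) and unfolded protein (0.00042 to 0.745). The unfolded protein list reversed without KO2, and its 0.00042 is from the fit without KO1, which kept the higher direction. Acta1 reversed as well (log2 change -0.30 to 1.39). The cause of these reversals was not tested. Of 21 genes named by their change 18 passed under every alternative in which they were tested (Col5a2, Col6a2 and Slc38a1 were not tested in all), and of 92 list examples that passed, 53 did. At this depth genes under about 1 CPM rest on few counts.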

Other observations

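All tests in this part were chosen after the data were seen, and no explanation is offered for them. Many genes of the spliceosome and of ribosome biogenesis fell in the KO cells, beside those of the cell cycle. Among 321 KEGG pathways annotated in the deposited table, 27 passed the camera test, 17 lower and 10 higher, and 0 passed with an estimated correlation (lowest adjusted p = 0.881 with an estimated correlation). Of 128 spliceosome genes 88 fell, 4 rose and 36 did not pass, and of 74 genes of ribosome biogenesis 46 fell, 0 rose and 28 did not pass (adjusted p = 8.3e-12 and 1.1e-09). Without WT1, WT2, WT3, KO1 or KO2, in that order, the 88 spliceosome genes lower became 46, 59, 53, 99 and 98, the 4 higher became 4, 4, 4, 9 and 4, and the 46 ribosome biogenesis genes lower became 18, 21, 19, 54 and 63. Of 108 lysosome genes 47 rose, 8 fell and 53 did not pass (adjusted p = 0.00817), and of 59 genes of ECM-receptor interaction 30 rose, 5 fell and 24 did not pass (adjusted p = 0.0179). In the same order, the 47 lysosome genes higher became 21, 26, 23, 52 and 65 and the 8 lower became 3, 4, 5, 23 and 15. The 30 ECM-receptor genes higher became 13, 13, 16, 31 and 35 and the 5 lower became 2, 2, 2, 13 and 12. The pathway tests were not repeated with a library left out. Fibroblast markers rose as ECM-receptor genes did (median log2 change 2.70), among them Postn, Col1a1, Col6a1 and Col6a2. How many genes these sets share, such as collagens, was not counted, so their rises may not be separate. Some KEGG pathways close to lists that had passed did not pass. These pathways are not the same sets of genes as the lists (67 against 22 tested for p53), and their p was adjusted over all 321. The p53 signaling pathway had 15 genes higher and 20 lower of 67, in the lower direction (adjusted p = 0.714), against the higher direction of the p53 target list. With 1 library left out in the same order, its 15 higher became 8, 8, 8, 19 and 25 and its 20 lower became 8, 8, 9, 33 and 25. Glycolysis (adjusted p = 0.933), oxidative phosphorylation (adjusted p = 0.226), PPAR signaling (adjusted p = 0.758), fatty acid degradation (adjusted p = 0.226), fatty acid biosynthesis (adjusted p = 0.631) and steroid biosynthesis (adjusted p = 0.109) did not pass either.

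Members of the prolactin family on chromosome 13, best known from the placenta, were expressed in the WT cells and split in KO. Of 8 tested members 5 fell, 1 rose and 2 did not pass. Without WT1, WT2, WT3, KO1 or KO2 the 5 lower became 3, 3, 3, 5 and 5 and the 1 higher became 1, 1, 1, 2 and 1. Prl8a9 was at 285 ± 50.3 CPM (SD, n = 3) in WT and changed by -3.77 ± 0.43 (SE) in KO, with 12.3 CPM in KO1 and 29.3 CPM in KO2, and its neighbour Prl8a1 changed by -4.06 on the log2 scale. Prl2c2 rose by 0.71, while Prl2c3 (369 and 398 CPM) did not pass; these have close copies and their reads are uncertain. The fetal growth genes Hmga2 (80.5 CPM in WT, 2.35 and 7.06 CPM in KO1 and KO2) and Igf2bp2 fell with Igf2bp3, while Igf2bp1 (37.1 and 35.0 CPM) and Lin28b (2.93 and 5.67 CPM, log2 change 0.95, adjusted p = 0.07) did not pass. Of 22 tested Hox genes 8 rose, 0 fell and 14 did not pass, with Hoxb9 at 15.0 CPM in WT and at 75.6 and 37.6 CPM in KO1 and KO2. For Hox genes, with libraries left out in the same order, the 8 higher became 2, 3, 3, 8 and 17 and the 0 lower became 0, 0, 0, 4 and 1. Of 16 tested chemokine genes 6 rose, 4 fell and 6 did not pass. Cxcl12, Cxcl14, Ccl2, Ccl7, Ccl27a and Ccl27b rose (Cxcl12 from 2.35 to 30.1 CPM), and Cxcl1 (225 CPM in WT, 8.91 and 20.2 CPM in KO1 and KO2) fell with Cxcl2, Cxcl3 and Cxcl5. Ccl27a and Ccl27b are close copies, and the division of reads between them is uncertain.

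Cfap53, Olfr1033, Wdr92 and Zbtb8b, on 4 different chromosomes, fell by nearly the same factor, 24.8, 23.9, 23.1 and 21.8, with little spread between KO1 and KO2 (80.5 and 74.5, 58.2 and 58.9, 45.2 and 39.7, and 27.2 and 27.3 CPM). They stand next to each other at the end of the ranking of the 10 largest falls, so close factors are partly built in. Other large falls were also close between KO1 and KO2, those of Zfp972 (7.24 and 8.89 CPM), Igf2bp3 (1.175 and 1.063 CPM) and Cxcl2 (0.93 and 0.77 CPM). Cxcl3, Cxcl5 and Slc38a1, with few counts in KO, were less close. Such stable falls, in KO libraries that otherwise varied widely, were not followed further. Reads shared with other loci were not resolved for Cfap53, Olfr1033, Wdr92 and Zbtb8b, so their falls as gene changes are uncertain.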
